A study of Oryza sativa with 6 samples.

How the data were processed

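The study measured total RNA from shoots of rice seedlings grown for 25 days under 11 h of light at 26 °C and 13 h of dark at 22 °C, extracted with Trizol and labelled with biotin by the standard Affymetrix procedure, per the labels' protocols. The 3 wild-type and 3 dst arrays are biological replicates, per the labels. The deposited values are 1 signal per probe set and array on a linear scale, and the software and scaling behind them are not given in the sources used here. The mean of each array after trimming 2% of the values at either end was 500.1, so each array appears to have been scaled to a common level before deposit. Scale, trimming and any floor are read from the values and not stated. No detection calls were used.

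Values under 1 were set to 1 and log2 was taken. The 187 control and reporter probe sets were left out, which left 57194 rice probe sets. Those with a mean log2 value under the 40th percentile (a signal of 70.5) were removed, which left 34316. The arrays were not normalized again, because their median log2 signals lay within 0.5 of one another. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of single genes come from this model. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

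Genes were named through the platform annotation and an NCBI RefSeq gene table of assembly ASM3414082v1. Of the rice probe sets, 22436 (39.2%) have 1 gene, 95 have several and 34663 have none in that annotation, and the gene of each of these 22436 probe sets was found in the gene table. Where a gene had several probe sets, the probe set with the highest mean stood for it. The table was used for names and for the order of genes only, since no genome build is named for the array values. It holds no gene descriptions, so gene lists whose themes were fixed before the data were examined, as patterns on descriptions, were rewritten as patterns on gene names, and a name in the table took the place of an informative description. The rewriting, and the choice of 7 further lists, came after the annotation was opened and before any comparison of the groups. In the rewriting some planned lists were split, merged or widened. Kinesins of cell division, planned with the cyclins, became part of a further list, and phosphate and iron starvation was split. Metallothionein genes entered with iron and zinc, COBRA-like genes with cellulose synthases, and floral organ genes with anther and pollen genes. Of 46 lists, 43 had at least 5 measured genes and were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera under an estimated correlation and fry beside it. Only 2245 of 16013 tested genes have a name, so each list covers part of its family.

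Named genes were chosen by a rule fixed before the data were examined. It takes certain catalase and ascorbate peroxidase genes, the 10 largest rises and 10 largest falls among named genes past the threshold, and members of each list. The rises and falls needed 3 dst values on one side of the 3 wild-type values and a higher group mean at or above the median of the tested probe sets. From the lists it takes the largest changes past the threshold, or the member with the smallest p. Members of lists that are only summarised were left out.

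The procedure was tested on simulated data with the real means of the 34316 probe sets and the spreads that the limma model estimated for them. That model draws spreads toward its mean-variance trend, so recovery under the observed spreads was not tested. Of 100 probe sets changed by 1 on the log2 scale 35 were recovered, and of 100 changed by 2, 73 were recovered, with 9 false among 117 calls. A list of 23 genes shifted by 0.5 was found among 43 lists and no other list was called. That shift was larger than the median change of any list called in the real data. The simulated noise was independent between genes, so false calls of lists whose members vary together were not tested. Alternatives covered normalization, the filter, an offset of 16, the variance model, array weights, the replicate number as a block, each array left out, the threshold, the probe sets per gene and the set test. A block for the third arrays, and a fit of replicates 1 and 2 alone, were added after seeing the data.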

Results

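Transcript levels were measured in shoots of 25-day-old rice seedlings of the japonica cultivar Zhonghua11 and of the dst mutant line, with 3 biological replicates of each. DST is known as a zinc finger transcription factor that acts on stomatal opening and on hydrogen peroxide levels in drought and salt responses. The question of the series was how the transcriptome of the mutant differs from that of the wild type in shoots grown without a stated stress treatment. Each of the 6 samples was read on its own Affymetrix rice array with 57381 probe sets, and the number of arrays limits the precision. The median signal of the rice probe sets lay between 117.6 and 140.9 per array. The third array of each group had a lower highest signal, 31461 in the wild type and 32620 in dst, against 41451 to 43119 on the other 4 arrays. The log2 ratio of 3' to 5' actin control signal lay between 1.83 and 2.05 in the wild type and between 1.81 and 2.01 in dst. The same ratio for the brighter set of GAPDH controls was higher on each dst array, at 1.01 to 1.36, than on each wild-type array, at 0.35 to 0.62. Its 5' probe set measured -0.71 ± 0.21 in dst, with an adjusted p of 0.941 over the control probe sets in limma. A dimmer GAPDH set, with a 5' signal of 22.6 in the wild type and 48.0 in dst, is not used here for the ratio. Its ratio leaned the other way, at 2.1 to 4.6 in the wild type and 1.2 to 2.8 in dst. The ratio of the ef1a controls overlapped, at -3.0 to -1.4 in the wild type and -4.0 to -1.6 in dst. DST itself, CKX2 and CATC were not analysed here.

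In dst shoots, OsBURP02, a BURP domain protein gene, was 4.61-fold higher than in the wild type, with a mean signal of 7679 ± 1245 against 1655 ± 177 (SD, n = 3). APG8D, of the ATG8 family of autophagy proteins, rose 4.57-fold, and OsPRR1, a pseudo-response regulator of the circadian clock family, rose 3.37-fold. OsMADS56, a MADS-box gene known to act in flowering time, rose 2.65-fold, from 1501 ± 88.3 to 3983 ± 341 (SD, n = 3), and lies in a stretch of 110 measured genes of which 17 changed. The largest falls among named genes were those of BC1L9, a gene of the COBRA-like family of cell wall proteins, 4.89-fold, and of the trypsin inhibitor gene OSE727A, 2.97-fold. The metallothionein gene OsMT-I-1b fell 2.60-fold, from 6150 ± 552 to 2374 ± 271 (SD, n = 3).

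Across the array, 317 of the 34316 tested probe sets passed an adjusted p of 0.05 in limma, of which 135 rose and 182 fell. Of these, 220 changed at least 2-fold, 85 upward and 135 downward. The 317 probe sets all had the 3 dst values on one side of the 3 wild-type values, as did 16.6% of the tested probe sets, where chance gives 10%. At gene level, with 1 probe set for each of 16013 genes, 72 genes rose and 86 fell, and 24 of these 158 genes carry a name in the annotation used. That annotation gives no single gene for 118 of the 317 probe sets. The other 199 read 188 genes, some of which are not among the 158 because a brighter probe set stands for them. Among 55 genes with a changed probe set and at least 1 other tested, the 95% intervals of some probe sets were apart in 28. The changes of several genes without a name were far larger, and these examples were chosen after their values were seen. LOC4341223 rose from a mean signal of 229 ± 80.7 to 7263 ± 539 (SD, n = 3). LOC4349188 went from 38.0 ± 22.2 to 2105 ± 369 in the probe set that stands for it, while its other probe set measured -0.86 ± 0.35 on the log2 scale (SE) and did not pass. LOC4340994 fell from 1263 ± 221 to 14.8 ± 5.55, and LOC4351143 from 453.9 ± 8.29 to 15.3 ± 0.924 (SD, n = 3). No detection calls were used, so the size of a fold against such low signals is uncertain.

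**Figure D1:**
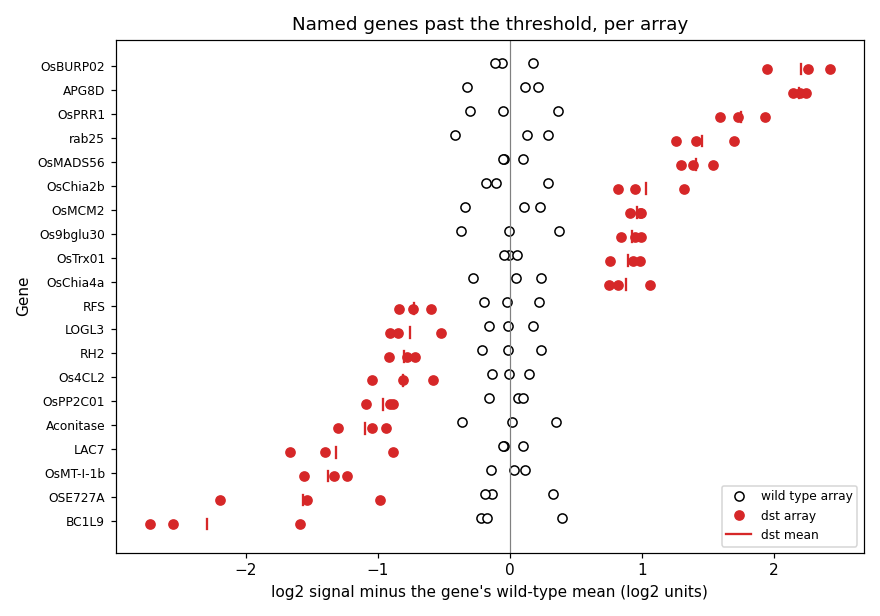
Signal of 20 named genes on each of the 6 arrays, as the log2 difference from the gene's wild-type mean, with open circles for wild type, filled circles for dst and a bar for the dst mean. OsBURP02 stands highest at 2.21 and BC1L9 lowest at -2.29, by the probe set that stands for each gene. In each gene the 3 dst arrays lie on one side of the 3 wild-type arrays, which the rule for choosing these genes required.

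Among the further named genes that rose, the dehydrin gene rab25 changed by 1.45 ± 0.21 on the log2 scale (SE), with an adjusted p of 0.0122 in limma. The chitinase genes OsChia2b and OsChia4a rose by 1.03 ± 0.17 and 0.88 ± 0.16. OsMCM2, a subunit of the replicative helicase, rose by 0.96 ± 0.17, the beta-glucosidase gene Os9bglu30 by 0.93 ± 0.18 and the thioredoxin gene OsTrx01 by 0.89 ± 0.13. OsGER4, of the germin-like family, rose by 0.65 ± 0.11. In the other direction, the laccase gene LAC7 fell from 5232 ± 305 to 2151 ± 605 (SD, n = 3), a log2 change of -1.32 ± 0.18. Aconitase changed by -1.10 ± 0.18, OsPP2C01, a protein phosphatase of the 2C class, by -0.96 ± 0.12, and Os4CL2, a 4-coumarate:CoA ligase, by -0.81 ± 0.15. RH2, an RNA helicase gene, changed by -0.81 ± 0.14, LOGL3, of the LOG family of cytokinin-activating enzymes, by -0.76 ± 0.14, and RFS by -0.73 ± 0.13. The rule for naming genes, fixed beforehand, takes 21 of the 24 named genes that passed. It leaves out AP25, SAT4 and OsTDL1B, which are named here after their values were seen. Adjusted p over the 21 ran from 1.2e-04 for OsBURP02 to 0.0499 for Os9bglu30. OsBURP02 and Os9bglu30 were the only ones of the 21 with a second tested probe set, which gave 0.78 ± 0.12 for OsBURP02 and 0.75 ± 0.26 for Os9bglu30.

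OsBURP02, APG8D, OsMADS56 and OsMT-I-1b passed the threshold in all 16 alternative fits, while the other 17 of these 21 genes missed it in at least 1, with a highest adjusted p of 0.0888 to 0.244 per gene. The count of 317 probe sets fell to 115 without wild-type replicate 2, 177 without wild-type replicate 3, 138 without dst replicate 1 and 181 without dst replicate 2, and it was 80 without the variance trend and 532 with array weights. The excess of falls over rises depended on single arrays. It turned around without wild-type replicate 1, with 134 up and 124 down, and without wild-type replicate 2, with 62 up and 53 down, and it was wider without dst replicate 2, with 54 up and 127 down, and with median centring, with 102 up and 192 down. With the third arrays as a block, a grouping chosen after seeing the data, 606 probe sets passed, 292 upward and 314 downward. Replicates 1 and 2 alone gave 203, 78 upward and 125 downward, and 201 of these 203 differed in the same direction in the third pair of arrays, which is too small for a test by itself.

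Genes of DNA replication and the cell cycle stood higher in dst shoots as a group. Of 52 measured genes in this list, 44 had a higher mean in dst, with a median log2 change of 0.39. OsMCM2 alone passed over all genes, and 4 passed when adjusted over the list alone, among them the helicase subunit gene OsMCM6 at 1.08 ± 0.25. The cyclin gene CYCB1-1 measured 0.92 ± 0.27 and passed neither test. Of 34 genes for kinesins, motor proteins of which many act in cell division, 25 had a higher mean in dst, with a median log2 change of 0.33. None passed singly over all genes or when adjusted over the list alone. KIN14N measured 0.72 ± 0.18. Kinesins of cell division had been planned in the same list as the cyclins. The kinesin list was set apart after the annotation had been opened but before any comparison of the groups. In camera with a preset correlation, the adjusted p was 5.6e-07 for the replication and cyclin list and 5.7e-04 for kinesins. Both calls were lost with an estimated correlation, with adjusted p = 0.716 for each. In both lists the lowest array was wild-type replicate 3, and without it the medians were 0.26 and 0.25, with adjusted p of 3.2e-04 and 0.0316. The medians were 0.34 and 0.28 in replicates 1 and 2, and 0.45 and 0.38 in the third pair.

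Phenylpropanoid and lignin synthesis genes stood lower in dst as a group. Of 29 measured genes, LAC7 and Os4CL2 fell, none rose and 27 did not pass. A higher mean in dst was seen in 11 of the 29, with a median log2 change of -0.21. When adjusted over the list alone 9 passed, which include the laccase genes LAC4 at -0.69 ± 0.14 and LAC24 at -1.09 ± 0.29, and in the opposite direction 4CLL7 at 0.93 ± 0.20. Camera gave an adjusted p of 3.3e-04 with the preset correlation and adjusted p = 0.540 with an estimated correlation. The median was -0.22 in replicates 1 and 2, and -0.27 in the third pair of arrays.

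Of 24 genes for expansins and xyloglucan hydrolases, which act on cell wall extension, 15 had a higher mean in dst, with a median log2 change of 0.21. None passed over all genes and 1 passed when adjusted over the list alone, OsEXPB11 at 0.68 ± 0.15. The adjusted p in camera was 0.0314, adjusted p = 0.540 with an estimated correlation, and 0.216 without wild-type replicate 2. It was 0.0638 with no filter and also 0.0638 without the variance trend. As with the other shifted lists, the 3' to 5' ratio of the brighter GAPDH controls differed between the groups in the same samples. The actin and ef1a ratios overlapped between the groups, and a bearing of these ratios on the lists was not tested.

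**Figure D2:**
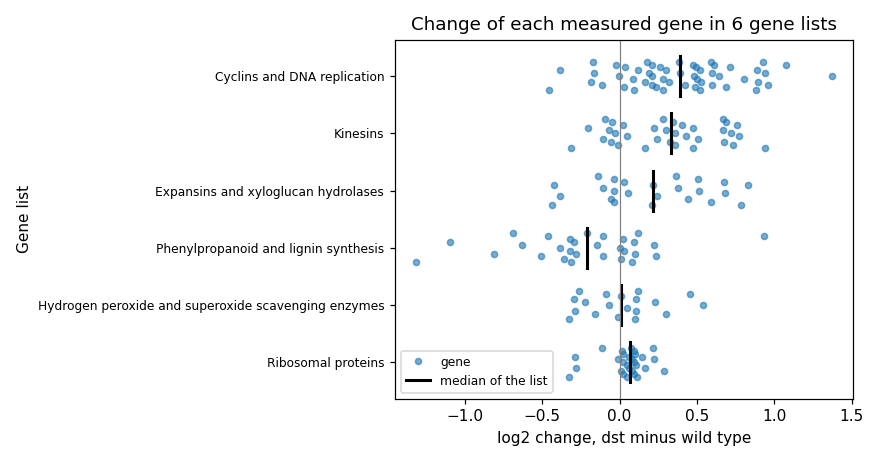
Log2 change between dst and wild type of each measured gene (points) in 6 gene lists, with the median of each list as a bar. The medians are 0.39 for replication and cyclin genes, 0.33 for kinesins, 0.21 for expansins and -0.21 for phenylpropanoid genes, beside 0.01 for scavenging enzymes and 0.07 for ribosomal proteins.

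Enzymes that remove hydrogen peroxide and superoxide showed no shift in a common direction as a list. Of 19 measured genes, none passed over all genes or when adjusted over the list alone, with a median log2 change of 0.01 and an adjusted p of 0.939 in camera. Its median and mean were above 0 and its test direction was downward. The catalase genes CAT-A and CAT-B measured -0.16 ± 0.12 and 0.05 ± 0.12, with 95% intervals of -0.44 to 0.12 and -0.22 to 0.32. The ascorbate peroxidase gene OsAPx01 measured 0.54 ± 0.20 with an adjusted p of 0.354 in limma, and OsAPx02 measured 0.01 ± 0.14. The list for oxidases that produce hydrogen peroxide has 14 measured genes and takes in germin-like genes by name. In it OsGER4 rose and 13 did not pass over all genes, while 2 of the 14 passed when adjusted over the list alone.

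Genes of water balance showed no call as lists either. None of 27 guard cell and potassium transport genes passed, with an adjusted p of 0.548 in camera, and OsHAK17 measured -0.66 ± 0.18. No gene of 23 aquaporin genes passed, with an adjusted p of 0.861, although a dimmer probe set of OsPIP2;1 measured -1.23 with an adjusted p of 0.0292 in limma, beside 0.06 for its brightest. Among 14 dehydrin and LEA genes rab25 rose and 13 did not pass, with an adjusted p of 0.484. Of the 25 genes of abscisic acid synthesis and signalling none passed, and the adjusted p was 0.861. Only 3 genes of stomatal development were measured, too few for a list test, and OsGRAS-38, also named OsSHR1, measured 0.90 ± 0.22 with an adjusted p of 0.133 in limma.

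In all, 4 of the 43 tested lists passed camera with the preset correlation, 3 higher and 1 lower in dst. None passed with an estimated correlation, where 3 lists had an unadjusted p under 0.05. By fry, which tests a list's own genes against no change in a common direction, none passed after adjustment and 8 had an unadjusted p under 0.05. The form of fry for change in either direction gave an unadjusted p of 8.6e-04 for the scavenging enzymes. It gave 4.9e-04 for the oxidases that produce hydrogen peroxide and 0.599 for the abscisic acid genes. Several other lists gave smaller values, such as 1.2e-07 for anther, pollen and floral organ genes and 1.5e-05 for protein phosphatases 2C. A small value was therefore not particular to the peroxide lists, and these values were not adjusted over the lists. Without dst replicate 3 the count of lists was 7.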

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

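The fit with the third arrays as a block and that with replicates 1 and 2 alone were chosen after seeing the data. The number of changed probe sets was 317, and with each array left out in turn it ranged from 115 to 281, with fewer samples in each fit. It was 80 without the variance trend, 532 with array weights, 122 at an adjusted p under 0.01, 606 with the third arrays as a block and 203 with replicates 1 and 2 only. The cause was not tested for the variance trend, the array weights or the block, while a stricter threshold lowers the count by construction. Fits with fewer samples also made new calls. Without wild-type replicate 1, 196 of the 258 calls were among the 317, and without dst replicate 3, 224 of 281 were. In the other settings the number of changed probe sets stayed within 1.5 times of 317. With the replicate block it was 463, of which 298 were among the 317. Replicate numbers 1 and 2 do not pair the samples, but the replicate 3 arrays of wild type and dst deviated alike. Deviations from the group means correlated, across probe sets, at 0.05, 0.05 and 0.20 for replicates 1, 2 and 3. Wild-type replicates 1 and 2 correlated best with other numbers. Each replicate 3 array correlated at -0.10 to -0.11 with replicates 1 and 2 of the other group. Deviations within a group cancel out by construction. These negative values and those near 0.05 therefore follow in large part from the 0.20 and add no separate support. In log2 signal, dst replicate 3 correlated at 0.9345 with wild-type replicate 3, above 0.9329 and 0.9307 with dst replicates 1 and 2. Wild-type replicate 3 correlated at 0.9281 and 0.9350 with wild-type replicates 1 and 2. The number of shifted lists was 4 and ranged from 3 to 7 with 1 array left out. It was 5 with the replicate block, 3 with no filter or without the variance trend, and 0 with an estimated inter-gene correlation. In that form of camera the smallest unadjusted p of any list was 0.0278, for iron and zinc homeostasis, with an adjusted p of 0.540. Since no list had a smaller p there, the loss of all calls does not show that list members vary together. The cause of the loss was not tested. The 21 genes past the threshold that the naming rule takes kept their call in 233 of 336 comparisons with alternatives. Among genes not past the threshold, OsAPx02 turned to -0.0264 with median centring and -0.0405 with replicates 1 and 2 only, and ranged from -0.124 to 0.0904 with 1 array left out. CAT-B ranged from -0.0062 to 0.139 with 1 array left out. The DST transcript was not analysed, so no other settings were run for it. Signal over background is not known without detection calls, which limits folds against low signals.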

Other observations

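The random placements in gene order, the fits for the third arrays, the tests on gained or lost segments, the test on ribosomal proteins and that on disagreement inside dense stretches were chosen only after the result was seen. Other gene groups held few changes past the threshold. In the clock and flowering list of 16 genes OsPRR1 rose, and GI, a clock gene, measured 0.52 ± 0.12 (SE) with an adjusted p of 0.0939 in limma. When adjusted over the list alone, both passed. Of 54 genes of iron and zinc homeostasis, OsMT-I-1b fell, 53 did not pass, and 18 had a higher mean in dst, with an adjusted p of 0.0540 in camera. This list passed in 7 of 18 alternatives, with adjusted p from 0.00941 without dst replicate 3 to 0.540 with an estimated correlation. Among 28 cytokinin genes LOGL3 fell and 27 did not pass, with a list adjusted p of 0.735. Among 20 chitinase and pathogenesis-related genes OsChia2b and OsChia4a rose and OSE727A fell, and 7 passed when adjusted over the list alone. The list had an adjusted p of 0.969 in camera, which tests for a shift in a common direction. Fry for change in either direction gave an unadjusted p of 5.1e-04. None of 187 control and reporter probe sets passed in limma, where 6 had an unadjusted p under 0.05.

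Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave 317 probe sets, and the highest of the other splits gave 0, with up to 3104 at an unadjusted p under 0.05 against 3613 in the real split. For lists, 3 of the 10 splits gave at least the real 4, with 6 as the highest other. The 4 splits with the third arrays of both groups on one side gave 0, 3, 4 and 6 lists, and the remaining 5 gave 0 to 3. With 10 splits no share under 0.05 can be reached for either count.

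Of 158 changed genes, 69 had another changed gene within 10 measured genes, against a mean of 28.2 and a maximum of 53 in 10000 random placements among genes of like signal (permutation p = 1e-04, the smallest these can give). Of the stretches denser than 95% of random maxima, the longer, from LOC9271722 to LOC4349258 and with OsMADS56 in it, had 17 changed genes among 110, 3 up and 14 down, and the other, from LOC4325690 to LOC4325215, had 7 among 40. Similar copies side by side are argued against as the whole cause, since 57 of 126 changed genes had a changed neighbour in the order of genes that leaves out those read by less specific probe sets (mean of random placements 21.6, permutation p = 1e-04). A gain or loss of the whole stretches is argued against by a median over all their genes no farther from 0 than -0.104 (95% bootstrap interval -0.199 to -0.00724), while smaller segments stay open, also outside them, where 16 of 27 neighbouring pairs went in opposite directions. Inherited segments that differ in sequence between the lines may account for the pattern and stay open, since the share of changed genes with a change of 8-fold or more was 8.33% inside and 8.96% outside the stretches (odds ratio 0.925, Fisher's exact p = 1), which does not decide it.

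Probe sets of the same changed gene often differed. In 28 of 55 genes with a changed probe set and at least 1 other tested, the 95% intervals of some pair were apart. OsChia2a gave 3.72 ± 0.27 and -2.47 ± 0.61, OsC3H2 gave 2.81 ± 0.33 and -0.71 ± 0.28, and Rictpi2, a triosephosphate isomerase gene, gave 2.15 ± 0.13 and -0.01 ± 0.12 (log2 change ± SE, chosen after their values were seen). Chance selection of extreme probe sets is argued against only by the third pair of arrays, 1 per group and too small for a test. There, 201 of 203 probe sets called on replicates 1 and 2 kept their direction. They exceeded the other probe sets of their genes by a median of 1.19 (30 genes). Sequence differences between the lines under single probe sets could produce this and stay open, as do transcripts of different structure, which were not tested, since the odds ratio of disagreement inside against outside the dense stretches was 1.20 (Fisher's exact p = 1).

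The call of the replication and cyclin list was lost with an estimated correlation (adjusted p = 0.716) and was not made by fry (adjusted p = 0.221). Its higher median of 0.39 was not carried by 1 array alone, although it fell to 0.26 without wild-type replicate 3, the lowest value with 1 array left out, nor by the difference between the third arrays and the others, as it was 0.34 in replicates 1 and 2 alone. A larger share of dividing tissue in the sampled dst shoots may account for it and cannot be told apart from a change within cells. The ribosomal protein list, which growing tissue expresses strongly, had a median of 0.065 and an adjusted p of 0.583 in camera, with 23 of 28 genes higher in dst.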
